A study of Mus musculus with 12 samples.

How the data were processed

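RNA was measured in B16F10 cells, a mouse melanoma cell line that is grown in dishes and forms pigmented tumours in mice. Per the labels' protocols, the cells were kept in DMEM with fetal bovine serum, total RNA was taken with TRIzol, and libraries were made with Illumina's stranded total RNA ligation kit after ribosomal RNA removal (Ribo-Zero Plus). The labels name a vector control (VC) and cells in which Bub1 was disrupted with CRISPR-Cas9 (Bub1KO), each without treatment or given a radiation dose of 8 Gy. The time between irradiation and RNA extraction, the number of Bub1KO lines and the guide sequence are not given in the sources used here. Each of the 4 groups has 3 libraries, and the group of each library was taken from its genotype and treatment labels.

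Reads were trimmed, aligned and counted with Trim Galore, cutadapt, STAR, SAMtools and HTSeq against GRCm38.p6 (mm10), per the submitters' processing notes, which give no versions and no order. The annotation release, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. Genes that overlap on opposite strands, antisense genes and near-identical copies therefore carry an extra uncertainty. The authors deposited 2 tables of 55421 genes each, 1 for the unirradiated and 1 for the irradiated pair of genotypes. Their sample columns hold a signal that is never negative: per the file headers and values, the authors divided each gene's read count by 1 size factor per library. The mean over all libraries in the deposited tables is the same in both, so the 12 libraries share 1 normalization. The deposited tables also give the authors' log2 fold change of VC over Bub1KO with its standard error, a test score (their quotient) and p-values with their adjusted form. The column names are those of a DESeq2 result table, per the file headers, although no source used here names the tool. No column of values was without a sample.

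Dividing each column by its smallest step returned whole reads for 100.0% of the values above 0 in every library (tolerance 0.01 of a read). The recovered reads in genes ranged from 19380726 to 33087366 per library and the size factors from 0.775 to 1.41. Gene positions were taken from the GENCODE M21 annotation of GRCm38 by gene identifier, 1-based. It matched 55240 of the identifiers, and 113 gene symbols stood on more than 1 identifier, of which the more abundant was used for lists.

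For raw counts the design named edgeR with TMM factors on all 12 libraries, and for normalized values limma-trend on the 6 libraries compared. Because the tables hold normalized values, the test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(value + 1), for 14721 genes with a value of at least 10 in at least 3 of the 12 libraries. Benjamini-Hochberg adjustment was applied over these genes with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Bub1KO was compared with VC separately without irradiation and after it, each on its own 6 libraries. The effect of irradiation within each genotype, and the interaction (the Bub1KO minus VC difference after irradiation minus the same difference without it), were fitted on all 12 libraries. The design had set these comparisons across the 2 tables aside unless raw counts were held. They were made because both tables share 1 normalization and whole reads were recovered, a decision taken after the values were seen. The mixture matters: comparisons fitted on 6 libraries take their spread from 6, and the same comparisons gave other gene counts when fitted on all 12.

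The design, 22 gene lists and the alternatives not said to be chosen later were fixed before the data were examined, and no list was chosen on these samples. The lists hold interferon-stimulated genes, double-stranded RNA sensing, interferon ligands, cytosolic DNA sensing, NF-kB cytokines and chemokines, MHC class I antigen presentation, stress granule proteins, p53 target genes, DNA double-strand break repair, G2/M and mitotic checkpoint genes (Bub1 itself left out), G1/S and replication genes, replication-dependent histones, melanocyte differentiation, dedifferentiated melanoma markers, the integrated stress response, extracellular matrix and TGF-beta response, cell death effectors, mitochondrially encoded mRNAs, abundant nuclear and structural noncoding RNAs, and markers of 3 other kinds of cell (leukocyte and macrophage, fibroblast and endothelial, keratinocyte and epithelial). Some genes stand in more than 1 list. Each list with at least 5 tested members was tested with limma's camera against all other tested genes, with the correlation between genes preset at 0.01 and adjustment over the lists of a comparison. The preset value can be too low for genes that move together, so each test was repeated with the correlation estimated from the libraries.

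Genes are named by a rule: Bub1 in every library; 12 readouts whatever their result (Cdkn1a, Mdm2, Ifnb1, Isg15, Ifit1, Ifih1, Ddx58, Cxcl10, Ccl5, H2-K1, Mitf, Tyr); from each list up to 2 genes that rose and 2 that fell with the smallest adjusted p past the threshold; and the 8 largest rises and 8 largest falls past the threshold with a mean of at least 1 CPM and no overlap between the groups' libraries, leaving out placeholder names and pseudogenes. Some genes that this rule names are not reported here. Any other named gene was chosen after its values were seen and is said to be so.

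The fits were tested on simulated counts drawn from the real means and library sizes, with 100 genes changed 1.5-fold and 100 changed 2-fold. For Bub1KO against VC without irradiation, limma recovered 43% of the 1.5-fold and 74% of the 2-fold changes (14529 genes, 10% of calls false). After irradiation the shares were 48% and 68% (14531, 4.92%), and for the interaction 18% and 67% (14526, 3.41%). For irradiation they were 56% and 75% in VC (14519, 5.76%) and 53% and 85% in Bub1KO (14513, 4.83%). Each comparison was drawn once, so differences such as 10% against 4.92% may be chance. DESeq2's calls were 10.7% to 14.5% false. Camera called 0 of 20 unchanged lists in each comparison. Genes were drawn independently, so this says nothing about lists whose genes move together.

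The alternatives were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, TMM factors, library sizes without the 20 most abundant genes, no filter beyond 1 read, a filter of 1 CPM in 3 libraries, the other set of libraries in the fit, the replicate number as a block, a pseudocount of 0.1, a minimum fold of 2, and leaving out each library in turn. The deposited size factors stand where median-ratio factors were planned, so TMM was the alternative. Removal of each library's trend with the GC content of the longest transcript (lowess, span 0.3; 99.9% of the tested genes have a value), edgeR, TMM, the fit of both genotype comparisons on all 12 libraries and the overlaps without each library were added after seeing the data. Of these, edgeR with TMM factors on all 12 libraries is the test that the design named for raw counts. In a simulation of a GC trend in the unirradiated comparison (14505 genes, 2-fold changes), the removal of GC trends raised recovery from 61.5% to 76.5% and false calls from 4 to 16.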

Results

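Gene expression was measured by RNA-seq in 12 libraries of B16F10 cells, a mouse melanoma line, with 3 libraries in each of 4 groups. Vector control (VC) cells and cells with CRISPR-disrupted Bub1 (Bub1KO) were each left untreated or given 8 Gy of radiation. The series asks how a lack of Bub1 makes melanoma cells respond differently to radiation, and its title names double-stranded RNA, viral mimicry and stress granules. Reads in genes per library were 29918801, 19380726 and 20324092 in untreated VC, 24519778, 30265326 and 23975180 in untreated Bub1KO, 33087366, 26367845 and 21596733 in irradiated VC, and 22618141, 23538006 and 22702873 in irradiated Bub1KO. Between 20153 and 21408 genes had at least 1 read in the unirradiated libraries and 21960 to 23570 in the irradiated ones. Reads of mitochondrial genes made up 2.31% to 2.93% of the unirradiated libraries and 3.53% to 3.93% of the irradiated ones. No label says that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

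The first principal component held 60.2% of the variance and separated irradiated from unirradiated libraries, and the second held 14.1% and separated the genotypes. Bub1KO without irradiation, replicate 1, stood apart from the other 2 libraries of its group. The chi-square per gene between it and replicates 2 and 3 was 53.99 and 50.34, against 7.865 between replicates 2 and 3 and 5.889 to 19.12 within the other groups. Its GC-rich genes were low relative to its GC-poor genes, with a log2 gap of -0.906 against 0.0432 and 0.123 in the other 2. This gap was -0.478 to -0.183 in untreated VC and 0.0862 to 0.516 in the irradiated libraries. As it differs between groups, removing GC trends can also take away part of any real change tied to GC content, with irradiation or genotype.

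**Figure D1:**
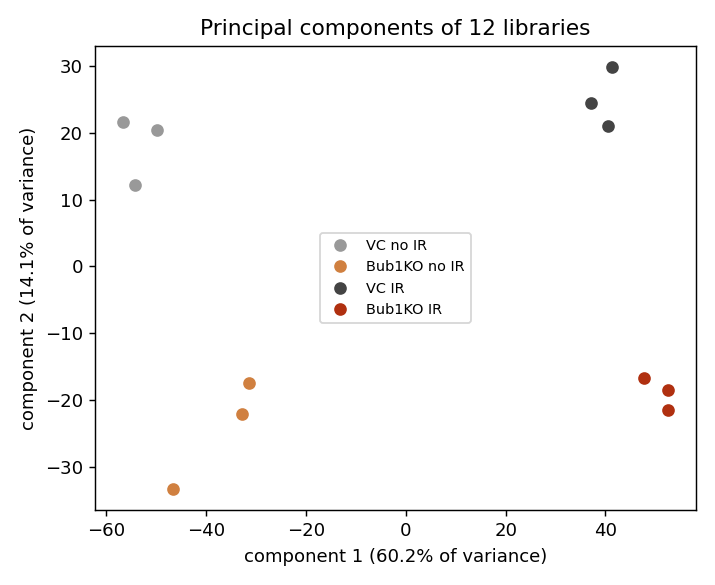
Scores of the 12 libraries (points) on the first 2 principal components of the log2 values, in score units, coloured by group. Component 1 (60.2% of the variance) runs from unirradiated (left) to irradiated (right) and component 2 (14.1%) from Bub1KO (bottom) to VC (top).

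Bub1, which encodes a kinase of the spindle assembly checkpoint (ENSMUSG00000027379.13, GRCm38 chromosome 2, 127801122 to 127831865), was lower in every Bub1KO library than in every VC library of the same treatment. Normalized counts were 2752, 3185 and 2859 in untreated VC (mean 2932 ± 226 SD) and 1834, 1565 and 1588 in untreated Bub1KO (1662 ± 149), which is 56.7% of VC. After irradiation they were 1484, 1461 and 1507 in VC (1484 ± 22.8) and 886, 989 and 1119.8 in Bub1KO (998 ± 117), which is 67.3% of VC. The difference was -0.82 log2 (SE 0.101, limma adjusted p = 0.003) without irradiation and -0.58 (SE 0.0797, limma adjusted p = 0.00019) after it, and the 2 differences were not distinguishable (interaction 0.24, limma adjusted p = 0.498). A CRISPR deletion or insertion of a few bases need not remove the transcript, and reads were not split by exon, so these counts show lower Bub1 RNA and not whether the protein was lost.

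**Figure D2:**
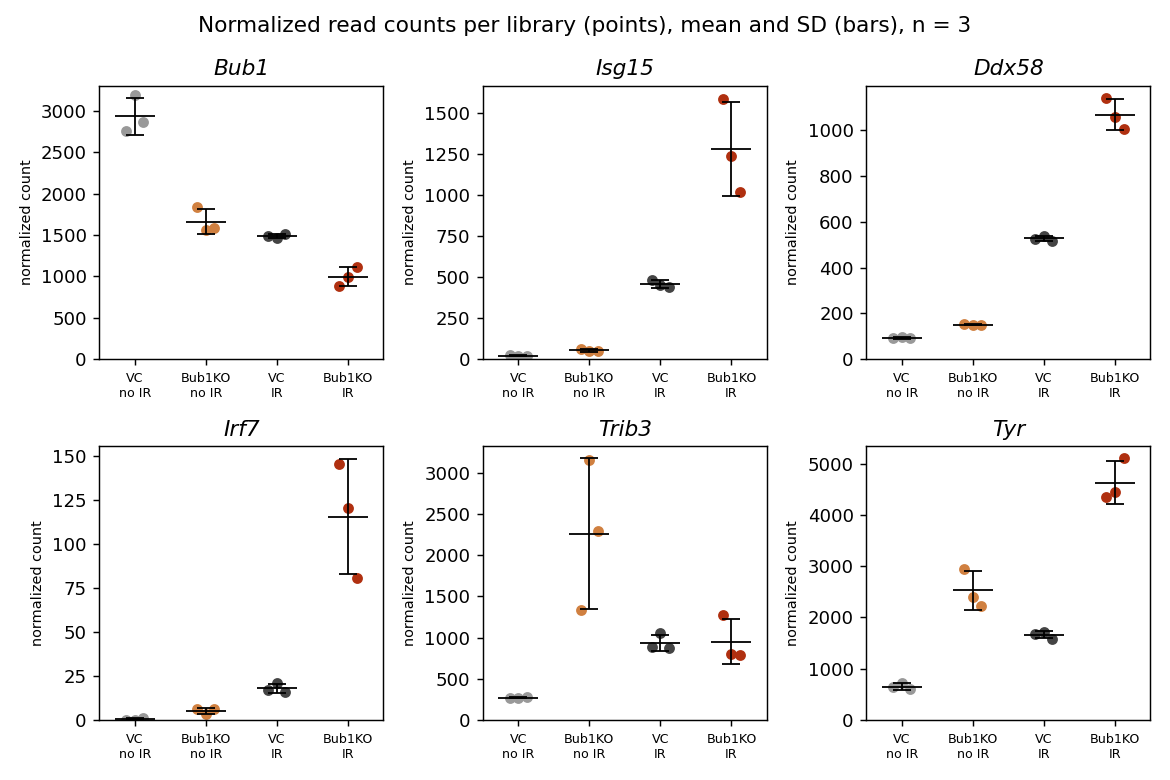
Normalized read counts (y axis, from 0, a separate scale for each gene) of Bub1, Isg15, Ddx58, Irf7, Trib3 and Tyr in each library (points), with the group mean and SD (bars, n = 3). Bub1 means are 2932, 1662, 1484 and 998 and Trib3 means 271, 2261, 936 and 951 in untreated VC, untreated Bub1KO, irradiated VC and irradiated Bub1KO.

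The comparison of untreated cells asks what disruption of Bub1 changes without radiation. Genes of the integrated stress response, the program run by Atf4 when translation initiation is restrained or amino acids are short, were higher in Bub1KO. Of 28 tested members, 20 rose, 0 fell and 8 did not pass. Trib3, a pseudokinase that restrains Atf4 (GRCm38 chromosome 2, 152337422 to 152344032), went from 271 ± 7.72 to 2261 ± 915 normalized counts (log2 fold change 2.97, SE 0.257, limma adjusted p = 0.000517). Chac1, which breaks down glutathione, went from 153 ± 1.52 to 1130.4 ± 453, and Nupr1, a stress-induced chromatin protein, from 116 ± 21.4 to 692 ± 208. Adjusted over the list alone 25 members passed, all higher, and the median change was 0.93 (camera adjusted p = 5.3e-27, or adjusted p = 0.126 with an estimated correlation). In the replicate that stood apart Trib3 was at 1329, against 3159 and 2295 in the other 2 libraries, and without that replicate 26 members rose.

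Interferon-stimulated genes, which encode antiviral proteins, were modestly higher in untreated Bub1KO. Of 46 tested, 7 rose, 0 fell and 39 did not pass, and the median change was 0.31 (camera adjusted p = 1.58e-06, or adjusted p = 0.14 with an estimated correlation). Adjusted over the list alone 16 passed, 14 higher and 2 lower. Isg15, a ubiquitin-like modifier (GRCm38 chromosome 4, 156199424 to 156200818), rose from 22.2 ± 3.07 to 55.4 ± 7.65 (1.28, SE 0.212, limma adjusted p = 0.0115), and Ifi27 from 549 ± 18.7 to 949 ± 86.7. Ddx58, the RNA helicase RIG-I, which senses double-stranded RNA, rose from 93.6 ± 2.74 to 152 ± 3.44 (0.69, SE 0.1315, limma adjusted p = 0.0219). Of the other members that rose, Samd9l, Gbp2, Mx1 and Rsad2 are named here after their values were seen. Ddx58 was the 1 of 24 tested genes of double-stranded RNA sensing that passed (3 adjusted over the list alone; median -0.02, mean 0.08, camera adjusted p = 0.842). The RNA sensor Ifih1 was at 89.5 ± 7.75 in VC and 114 ± 8.94 in Bub1KO (limma adjusted p = 0.253), Ifit1 at 19.4 and 22.2 (limma adjusted p = 0.811) and the chemokine Cxcl10 at 164 and 108 (limma adjusted p = 0.0628). The list had 2, 1 and 3 members higher without VC replicate 1, 2 or 3 and 4 and 5 higher without Bub1KO replicate 2 or 3, with 0 lower each time, and 13 higher and 3 lower without Bub1KO replicate 1. The Ddx58 call ended without any 1 library except Bub1KO replicate 1 and that of Isg15 without VC replicate 2 or 3 or without a filter, with limma adjusted p of at most 0.119 and 0.0668.

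Pigment cell genes were higher in untreated Bub1KO. Of 23 tested genes of melanocyte differentiation 6 rose and 0 fell (11 passed adjusted over the list alone; median 0.25, camera adjusted p = 4.82e-08, or adjusted p = 0.0536 with an estimated correlation). Tyr, the tyrosinase that starts melanin synthesis (GRCm38 chromosome 7, 87424771 to 87493512), rose from 650 ± 60.8 to 2524 ± 377 (1.95, SE 0.126, limma adjusted p = 0.000147), and the ion channel gene Trpm1 from 309 ± 38.0 to 637 ± 26.2. Rab27a, Dct, Slc24a5 and Cited1, named after their values were seen, also rose. Their regulator Mitf was at 10494 ± 451 and 12504 ± 888 (limma adjusted p = 0.166). Of 9 dedifferentiated melanoma markers 2 fell, the growth factor receptor genes Ngfr (27.4 ± 4.14 to 4.97 ± 1.79) and Pdgfrb (12.9 ± 1.17 to 1.59 ± 0.547), and 0 rose (3 adjusted over the list alone; median -0.16, camera adjusted p = 0.328). The Ngfr call ended without a filter and that of Pdgfrb without VC replicate 1 (limma adjusted p of at most 0.0699 and 0.06).

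Matrix genes were lower in untreated Bub1KO. In the list of extracellular matrix and TGF-beta response 7 of 25 tested members fell and 1 rose (14 passed adjusted over the list alone; median -0.21, camera adjusted p = 0.00274, or adjusted p = 0.126 with an estimated correlation). Fn1, which encodes fibronectin, was at 1092 ± 54.1 in VC and 522 ± 63.4 in Bub1KO (-1.07, SE 0.114, limma adjusted p = 0.00149), and Ccn2, a matricellular growth factor gene, at 164 ± 13.7 and 59.3 ± 8.22. Ccn1, Smad7, Thbs1, Sparc and Tgfb2 fell as well and are named after their values were seen. The member that rose was Postn (402 ± 21.7 to 597 ± 84.1, limma adjusted p = 0.041), which also stands among the fibroblast markers. Its call ended when any 1 library other than Bub1KO replicate 1 was left out (limma adjusted p of at most 0.195).

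The largest falls in untreated Bub1KO brought several genes close to the detection floor. The limb and body-axis transcription factor gene Hoxd13 went from 353 ± 30.5 to 6.11 ± 2.58 (-5.69, SE 0.258, limma adjusted p = 2.15e-05), Hapln1, a hyaluronan link protein gene, from 953 ± 164 to 42.4 ± 3.52, and Capn6 from 402 ± 68.3 to 5.51 ± 2.60. Mtus1 was at 157 ± 27.2 in VC and 0.625 ± 0.554 in Bub1KO, the gap junction gene Gja1 at 83.5 ± 17.8 and 1.38 ± 1.20, Shisa2 at 105 ± 11.1 and 10.6 ± 2.01, the metalloprotease gene Adam12 at 716 ± 68.6 and 125 ± 10.2, and Etv5, an ETS transcription factor gene, at 429 ± 26.0 and 76.6 ± 24.99. In the other direction Dnah6, a gene of the ciliary dynein motor, was at 0.840 ± 1.46 in VC and 126 ± 16.8 in Bub1KO. Mgll, which encodes monoacylglycerol lipase, rose from 213 ± 30.2 to 1050.4 ± 246, Clu (clusterin) from 22.8 ± 4.77 to 119 ± 24.6, Pde1b from 9.52 ± 2.68 to 53.9 ± 6.30 and Ndufa4l2 from 4.49 ± 1.74 to 41.5 ± 20.6. The Ndufa4l2 call (limma adjusted p = 0.00912) ended without VC replicate 2 and without a filter, with limma adjusted p of at most 0.132.

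Among 18 tested genes of MHC class I antigen presentation 3 rose (Cd274, H2-T22 and H2-K1) and 1 fell (H2-M3), 9 passed adjusted over the list alone, and the median was 0.36 (camera adjusted p = 0.00106, or adjusted p = 0.14 with an estimated correlation). H2-K1 went from 100.4 ± 19.7 to 177 ± 26.5 (limma adjusted p = 0.0471). All 4 of these calls ended without any 1 VC library or without Bub1KO replicate 3 (limma adjusted p of at most 0.212), and reads of the closely related H2 genes may be shared between them. Stress granule proteins had 0 of 33 members past the threshold, also adjusted over the list alone, and a median of -0.15 (camera adjusted p = 0.000235, or adjusted p = 0.183 with an estimated correlation). Among 48 p53 target genes 2 rose (Eda2r, a TNF receptor family gene, from 32.1 ± 6.30 to 131 ± 30.8, and Sesn2) and 5 fell, of which Zmat3 and Sulf2 had the smallest p and Aen, Btg2 and Ccng1 were named after their values were seen. Adjusted over the list alone 14 passed, and the median was -0.12 (camera adjusted p = 0.251). The calls of Eda2r and Sesn2, like that of Chac1 above, ended without a filter, that of Zmat3 without VC replicate 2 and that of Sulf2 without any 1 VC library or a filter (limma adjusted p of at most 0.0568, 0.115, 0.0623, 0.0505 and 0.0662). Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases, was at 10501 ± 907 and 8274 ± 998 (limma adjusted p = 0.128), and Mdm2 at 2559 and 2199.8 (limma adjusted p = 0.269).

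No member of the lists of G2/M and mitotic checkpoint genes (52 tested, camera adjusted p = 0.44), G1/S and replication genes (50 tested, 0.173), replication-dependent histones (16 tested, 0.538), cytosolic DNA sensing (7 tested, median 0.01, mean -0.05, 0.554), cell death effectors (20 tested, 0.731) or mitochondrially encoded mRNAs (7 tested, 0.328) passed by limma in untreated cells, and 0 passed adjusted over each list alone. The G1/S list passed, downward, without a filter (camera adjusted p = 0.0405), and the mitochondrial list, downward, without Bub1KO replicate 1 (0.0241). Across all genes 2817 had an unadjusted p under 0.05 by limma, and DESeq2 called 1831. Brca1, from 2714 ± 93.6 to 4176 ± 252 (limma adjusted p = 0.00517), was the 1 change among 42 genes of DNA double-strand break repair (2 adjusted over the list alone; median -0.003, mean 0.03, camera adjusted p = 0.538). Among 18 NF-kB cytokines and chemokines Tnfaip2 rose (582 ± 25.7 to 1173 ± 198) and Cx3cl1 fell (69.5 ± 15.0 to 21.9 ± 9.29), with 5 passing adjusted over the list alone (camera adjusted p = 0.972), and Ccl5 was at 21.6 and 28.9 (limma adjusted p = 0.346). Among 7 abundant noncoding RNAs 1 fell, Kcnq1ot1, an antisense transcript (517 ± 49.9 to 346 ± 49.0, limma adjusted p = 0.0477; 5 adjusted over the list alone; camera adjusted p = 0.636). The calls of Cx3cl1 and Kcnq1ot1 ended without any 1 VC library, and that of Kcnq1ot1 also without Bub1KO replicate 2 or 3 (limma adjusted p of at most 0.221 and 0.219). The Tnfaip2 call ended without a filter (0.0679).

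In all, 591 of 14721 genes differed between untreated Bub1KO and VC by limma at an adjusted p under 0.05, 340 higher and 251 lower, and 216 of them by at least 2-fold. The count was 2736 without the replicate that stood apart, 185, 172 and 242 without VC replicate 1, 2 or 3, and 301 and 298 without Bub1KO replicate 2 or 3. It was 1769 with all 12 libraries in the fit, 1831 with DESeq2, 1690 with GC trends removed (and with them possibly part of a real change) and 1759 with edgeR, by which more were lower (917) than higher (842). The authors' deposited table holds 1829 genes at an adjusted p under 0.05.

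After irradiation, where the comparison asks what Bub1 disruption changes in irradiated cells, interferon-stimulated genes were higher in Bub1KO nearly throughout the list. Of 46 tested, 42 rose, 0 fell and 4 did not pass, with a median change of 0.93 (43 passed adjusted over the list alone, 42 higher and 1 lower; camera adjusted p = 3.23e-24, or adjusted p = 0.197 with an estimated correlation). Irf7, the transcription factor that amplifies interferon production (ENSMUSG00000025498.15, GRCm38 chromosome 7, 141262706 to 141266481), was at 18.0 ± 2.53 in irradiated VC and 116 ± 32.6 in irradiated Bub1KO (2.58, SE 0.224, limma adjusted p = 4.86e-06). Isg15 was at 460 ± 23.1 and 1283 ± 288 (1.46, SE 0.123, limma adjusted p = 4.18e-06), Ddx58 at 527 ± 9.20 and 1067 ± 68.2 (1.014, SE 0.0716, limma adjusted p = 8.65e-07) and Ifi27 at 2075 ± 59.0 and 4878 ± 254. Ifih1 was at 345 ± 1.71 and 462 ± 24.4 (0.42, limma adjusted p = 0.00181) and Ifit1 at 655 ± 14.1 and 957 ± 174 (0.53, limma adjusted p = 0.002). The Ifit1 call ended with all 12 libraries in the fit and without a filter (limma adjusted p of at most 0.114).

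Of 24 genes of double-stranded RNA sensing 12 rose and 1 fell (13 adjusted over the list alone). The median was 0.17 (camera adjusted p = 0.000597, or adjusted p = 0.131 with an estimated correlation). It shares genes such as Ddx58 with the interferon list, so the 2 are not independent. Of 11 interferon ligand genes, Ifna2 and Ifne had 1 read each over the 12 libraries and the others, Ifnb1 among them, 0. None was testable. In MHC class I antigen presentation 10 of 18 genes rose and 3 fell (13 adjusted over the list alone; median 0.22, camera adjusted p = 0.00419, or adjusted p = 0.277 with an estimated correlation). H2-K1 was at 336 ± 31.2 and 663 ± 48.9 (0.98, SE 0.0915, limma adjusted p = 8.84e-06), and B2m, the light chain of MHC class I, at 5598 ± 149 and 7802 ± 260.2. The genes that fell were Psmb10, H2-M3 and Erap1, the last named after its values were seen. The calls of Psmb10 and H2-M3 each ended in 3 settings (adjusted p of at most 0.188 and 0.108). Among 18 NF-kB cytokines and chemokines 4 rose and 5 fell (9 adjusted over the list alone; camera adjusted p = 0.477), with Tnfaip2 and Il15 higher and Lif and Cx3cl1 lower (the Cx3cl1 call ended without a filter at 0.0786). Nfkbia and Csf1 (higher) and Nfkb2 and Nfkb1 (lower) are named after their values were seen. The chemokine gene Ccl5 was lower in irradiated Bub1KO (884 ± 33.9 and 646 ± 81.6, -0.46, limma adjusted p = 0.00212, ended without a filter at 0.0736), and Cxcl10 was at 501 ± 48.9 and 560.4 ± 73.0 (limma adjusted p = 0.275).

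The integrated stress response list, higher in untreated Bub1KO, had 3 members higher and 7 lower among 28 after irradiation (10 adjusted over the list alone; median -0.04, camera adjusted p = 0.423). Trib3 was at 936 ± 98.6 in irradiated VC and 951 ± 278 in irradiated Bub1KO, and Chac1 at 485 ± 39.3 and 441 ± 94.5. The clearest members were Nupr1 and Sars (higher) and Phgdh and Shmt2 (lower), all of whose calls ended with all 12 libraries in the fit (adjusted p of at most 0.205, 0.102, 0.136 and 0.0811). The third riser, Ddit4, is named after its values were seen. Without Bub1KO replicate 1 the list's median was -0.11 (camera adjusted p = 0.0236).

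Pigment genes again stood higher in Bub1KO. Of 23 genes of melanocyte differentiation 11 rose and 3 fell (16 adjusted over the list alone; median 0.14, camera adjusted p = 0.00167, or adjusted p = 0.197 with an estimated correlation). Tyr was at 1659 ± 67.1 and 4628 ± 420.1 (1.48, SE 0.0687, limma adjusted p = 2.07e-08), and Cited1, a transcriptional coactivator gene, at 820.1 ± 67.4 and 3389 ± 382. Mitf was at 12637 ± 726 and 11720 ± 718 (limma adjusted p = 0.209). The members that fell were Kit, Mreg and Mlph, the last named after its values were seen. The Kit and Mreg calls ended with all 12 libraries in the fit (adjusted p of at most 0.0736 and 0.174). Of 9 dedifferentiated melanoma markers 1 rose (Loxl2) and 2 fell (Ngfr, from 71.6 ± 9.35 to 17.5 ± 4.02, and Jun). Adjusted over the list alone 4 passed (median -0.17, camera adjusted p = 0.291). The Loxl2 and Jun calls ended without a filter (0.0602 and 0.0543). In the list of extracellular matrix and TGF-beta response 14 of 25 fell and 4 rose (19 adjusted over the list alone; median -0.43, camera adjusted p = 0.000377, or adjusted p = 0.131 with an estimated correlation). Fn1 was at 2754 ± 330 and 908 ± 136 (-1.60, SE 0.104, limma adjusted p = 4.24e-07) and Ccn2 at 169 ± 15.1 and 50.5 ± 1.75, while Timp3, an inhibitor of matrix proteases, and Mmp14 rose. The other risers, Postn and Mmp2, are named after their values were seen.

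Cell cycle genes were slightly lower in irradiated Bub1KO. Of 52 G2/M and mitotic checkpoint genes 25 fell and 1 (Pttg1) rose, with a median of -0.19 (33 adjusted over the list alone; camera adjusted p = 3e-06, or adjusted p = 0.277 with an estimated correlation). Of 50 G1/S and replication genes 22 fell and 0 rose, with a median of -0.17 (24 adjusted over the list alone; camera adjusted p = 1.66e-06, or adjusted p = 0.277 with an estimated correlation). Foxm1, a transcription factor of mitotic genes, was at 2715 ± 115 and 2063 ± 74.2, the checkpoint gene Bub3 at 5085 ± 125 and 3913 ± 199.9, and the replicative helicase gene Mcm2 at 8487 ± 373 and 6318 ± 212. Among 33 stress granule proteins 13 fell and 1 (Zfand1) rose (15 adjusted over the list alone; median -0.13, camera adjusted p = 0.000243, or adjusted p = 0.277 with an estimated correlation), with Usp10 and Atxn2l the clearest falls. The Zfand1 call ended without a filter (0.0744) and that of Atxn2l with all 12 libraries in the fit (at most 0.0845). Among 42 repair genes 3 rose and 12 fell (16 adjusted over the list alone; camera adjusted p = 0.249), Brca1 being at 5296 ± 95.2 and 7158 ± 422. Rad51c rose too, a call that ended without a filter (0.053), and so did Xrcc3, named after its values were seen. Among 48 p53 targets 6 rose and 15 fell (26 adjusted over the list alone; median -0.09, camera adjusted p = 0.0596), with Eda2r higher (157 ± 6.35 and 398 ± 35.0), Gtse1 and Btg2 lower, Mdm2 at 5581 ± 162 and 4527 ± 226 (limma adjusted p = 0.00151) and Cdkn1a at 30718 ± 897 and 29893 ± 1377 (limma adjusted p = 0.64). Without Bub1KO replicate 2 the p53 list passed (camera adjusted p = 0.0208).

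The other lists did not pass as a whole in irradiated cells. Of 16 replication-dependent histones 0 rose and 4 fell (4 adjusted over the list alone; median -0.28, camera adjusted p = 0.0853), with Hist1h2bc and Hist1h3d the clearest and Hist2h2be and Hist1h4i named after their values were seen. The list passed with edgeR on 12 libraries (0.0257) and without a filter (0.000355), and the Hist1h3d call ended with DESeq2 and with all 12 libraries in the fit (at most 0.0671). Of 20 cell death effectors 5 rose and 4 fell (10 adjusted over the list alone; camera adjusted p = 0.972), with the gasdermin gene Gsdmd higher and Bcl2l1, which encodes the anti-apoptotic Bcl-xL, lower (3065 ± 70.3 and 2181 ± 60.9). Bmf was higher and Hrk lower (a call that ended with DESeq2), and Mlkl, Gsdme and Bid (higher) and Bcl2 and Xiap (lower) are named after their values were seen. The median of this list was 0.01 and its mean -0.05, with camera upward. Cytosolic DNA sensing had 0 of 7 past the threshold by limma, also adjusted over the list alone (median -0.01, mean 0.01, camera upward, adjusted p = 0.972). Mitochondrially encoded mRNAs had 1 higher (mt-Nd6) and 1 lower (mt-Nd2) of 7 (3 adjusted over the list alone; camera adjusted p = 0.526), and both calls ended with all 12 libraries in the fit (at most 0.295 and 0.204). Abundant noncoding RNAs had 3 higher (Malat1, Neat1 and, named after its values were seen, Gas5) and 1 lower of 7 (5 adjusted over the list alone; median -0.13 and mean -0.03, although camera placed the list upward, adjusted p = 0.865). Malat1 was at 49047 ± 4256 and 76312 ± 8291 and Rn7sk at 254 ± 34.0 and 131 ± 13.2.

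Several of the largest falls seen without radiation were again among the largest between the irradiated genotypes. Hoxd13 was at 153 ± 3.81 in VC and 3.45 ± 1.24 in Bub1KO, Hapln1 at 259 ± 35.1 and 26.8 ± 7.59, Capn6 at 201.2 ± 22.5 and 9.63 ± 1.64, Gja1 at 161 ± 11.7 and 5.86 ± 1.64, Mtus1 at 142 ± 6.33 and 2.06 ± 1.79 and Shisa2 at 55.0 ± 6.04 and 5.499 ± 1.19. Pmepa1, a TGF-beta feedback gene, fell as well (151 ± 18.3 and 37.1 ± 10.9). Rpl36, a ribosomal protein gene, was at 11682 ± 5472 and 2663 ± 187 (-2.04, SE 0.21, limma adjusted p = 1.95e-05). Its values spread widely between libraries, its near-identical copies make its reads uncertain, and its call ended with edgeR on 12 libraries (adjusted p = 0.0716). Among the rises Car9, a carbonic anhydrase gene, was at 196 ± 7.31 and 889 ± 67.9 (2.18, SE 0.085, limma adjusted p = 1.72e-08), Dnah6 at 2.02 ± 2.62 and 192 ± 5.95, Mgll at 1517 ± 100.2 and 6788 ± 1103, the potassium channel gene Kcnj13 at 25.2 ± 6.84 and 122 ± 12.2, Wfdc3 at 62.3 ± 14.2 and 247 ± 22.1, and Pon3 at 14.7 ± 5.08 and 67.7 ± 11.2.

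Limma called 4512 genes between irradiated Bub1KO and VC, 2104 higher and 2408 lower, of which 404 differed by at least 2-fold. The count was 2105 with all 12 libraries in the fit, 2539 with DESeq2, 2454 with edgeR and 2062 without a filter, and the authors' deposited table holds 2533 genes at an adjusted p under 0.05. Which direction held more genes depended on the setting: 1382 were higher and 1072 lower with edgeR on 12 libraries, 1109 and 953 without a filter, 1085 and 1020 by limma on 12 libraries, and 220 and 184 at 2-fold.

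The 2 genotype comparisons share no library. Genes higher in Bub1KO in both numbered 251, where 48.6 would be shared by independent lists (Fisher's exact test, two-sided, p = 2.53e-140), and genes lower in both 196, where 41.1 would be (p = 1.2e-105), while 7 genes went opposite ways. Across genes, which are not independent replicates, the 2 sets of log2 fold changes had a Pearson correlation of 0.53. The shared total of 447, where 89.7 would be shared by independent lists, became 1290 (417) without the untreated Bub1KO replicate that stood apart and 147 to 254 (25.8 to 45.4) without any 1 of the other 5 untreated libraries.

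Irradiation, compared with no treatment within each genotype, raised p53 target genes. In VC 40 of 48 rose and 0 fell (40 adjusted over the list alone; median 1.13, camera adjusted p = 2.73e-16, and 0.00017 with an estimated correlation). In Bub1KO 38 rose and 0 fell (39 adjusted over the list alone; median 0.96, camera adjusted p = 2.11e-16, and 0.000171 with an estimated correlation). Cdkn1a (GRCm38 chromosome 17, 29090976 to 29100727) went from 10501 ± 907 to 30718 ± 897 in VC (1.55, SE 0.0892, limma adjusted p = 2.27e-08) and from 8274 ± 998 to 29893 ± 1377 in Bub1KO (1.86, SE 0.0892, limma adjusted p = 4.27e-09). Mdm2, the ubiquitin ligase that restrains p53, went from 2559 ± 95.4 to 5581 ± 162 and from 2199.8 ± 247 to 4527 ± 226, and Dglucy from 143 ± 8.14 to 1109.5 ± 29.9 and from 149.8 ± 3.92 to 1291 ± 52.96. Bub1 itself fell by 0.98 (limma adjusted p = 1.77e-06) in VC and by 0.74 (limma adjusted p = 2.21e-05) in Bub1KO.

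Interferon-stimulated genes rose with irradiation in both genotypes, 39 of 46 in VC (39 adjusted over the list alone; median 1.495, camera adjusted p = 1.99e-15, and 0.0244 with an estimated correlation). In Bub1KO 44 of 46 rose (45 adjusted over the list alone; median 2.14, camera adjusted p = 3.92e-23, and 0.0141 with an estimated correlation). In neither did any fall. Isg15 rose by 4.32 log2 in VC (SE 0.161, limma adjusted p = 4.53e-10) and by 4.49 in Bub1KO (SE 0.161, limma adjusted p = 3.55e-10), Ifit1 by 5.04 and 5.39, Ifih1 by 1.94 and 2.02, and Ddx58 by 2.48 and 2.81. Ifit3b, a near-identical neighbour of Ifit3 with which it may share reads, was among the largest rises in Bub1KO (13.8 ± 2.38 to 372 ± 117). Double-stranded RNA sensing had 11 members higher and 7 lower of 24 in VC (18 adjusted over the list alone; median 0.15, camera adjusted p = 0.162). In Bub1KO 12 were higher and 6 lower (19 adjusted over the list alone; median 0.28, camera adjusted p = 0.0141, and 0.0382 with an estimated correlation). Dicer1, which processes double-stranded RNA, fell in both (2608 ± 122 to 1885 ± 58.8 in VC). Cytosolic DNA sensing had 1 higher and 5 lower of 7 in VC (6 adjusted over the list alone; camera adjusted p = 0.0818). In Bub1KO 1 was higher and 4 lower (5 adjusted over the list alone; camera adjusted p = 0.251). Enpp1 went from 94.2 ± 9.87 to 55.8 ± 4.17 in VC. Samhd1 fell and Irf3 rose in VC, and Dnase2a and Tbk1 fell and Tmem173 rose in Bub1KO. Cgas, named after its values were seen, fell in both. The calls of Samhd1, Irf3, Tbk1 and Tmem173 each ended in at least 1 setting (adjusted p of at most 0.0707, 0.566, 0.132 and 0.0849).

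Chemokine and antigen presentation genes rose together with these. Ccl5 went from 21.6 ± 2.35 to 884 ± 33.9 in VC (5.30, SE 0.124, limma adjusted p = 9.15e-12) and from 28.9 ± 0.530 to 646 ± 81.6 in Bub1KO (4.43, SE 0.124, limma adjusted p = 5.14e-11), and Cxcl10 from 164 ± 14.3 to 501 ± 48.9 and from 108 ± 12.9 to 560.4 ± 73.0. The NF-kB list had 11 higher and 1 lower (Nfkb1) of 18 in VC (12 adjusted over the list alone; median 0.98, camera adjusted p = 0.00227, and 0.0245 with an estimated correlation). In Bub1KO it had 13 higher and 1 lower (Nfkb1) (14 adjusted over the list alone; median 0.82, camera adjusted p = 0.000209, and 0.0141 with an estimated correlation). MHC class I antigen presentation had 14 higher and 2 lower (Calr and Pdia3) of 18 in VC (16 adjusted over the list alone; median 0.77, camera adjusted p = 2.98e-05, and 0.0206 with an estimated correlation). In Bub1KO 13 were higher and 0 lower (14 adjusted over the list alone; median 0.67, camera adjusted p = 2e-05, and 0.017 with an estimated correlation). Tap1, a subunit of the peptide transporter and also a p53 target, went from 29.9 ± 4.38 to 331 ± 12.6 in VC and from 39.2 ± 2.37 to 315 ± 14.0 in Bub1KO. H2-K1 went from 100.4 ± 19.7 to 336 ± 31.2 and from 177 ± 26.5 to 663 ± 48.9. The falls of Calr and Pdia3 in VC ended in 2 and 8 settings (at most 0.0753 and 0.196). Markers of other cells moved with these groups: Lyz2 rose in VC (4.78 ± 0.555 to 68.8 ± 4.39) and Bub1KO (9.97 ± 2.03 to 62.3 ± 7.38), and Cd68 rose from 24.1 ± 2.08 to 113 ± 15.9 and from 19.4 ± 1.45 to 216 ± 7.54.

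Proliferation genes fell after irradiation. Of 52 G2/M and mitotic checkpoint genes 50 fell in VC (52 passed adjusted over the list alone; median -0.87, camera adjusted p = 1.45e-22, and 0.00854 with an estimated correlation). In Bub1KO 51 fell (52 adjusted over the list alone; median -1.05, camera adjusted p = 2.47e-27, and 0.00464 with an estimated correlation). Pttg1 was the 1 gene higher in each. In VC the Pttg1 call ended in 7 settings (at most 0.151). Of 50 G1/S and replication genes 47 fell in VC (48 adjusted over the list alone; median -0.84, camera adjusted p = 4.64e-22, and 0.00778 with an estimated correlation). In Bub1KO 49 fell (49 adjusted over the list alone; median -0.98, camera adjusted p = 8.68e-27, and 0.00407 with an estimated correlation). In neither did any rise. Mki67, the Ki-67 proliferation marker, went from 15452 ± 398 to 5665 ± 283 in VC (-1.45, SE 0.0819, limma adjusted p = 2.03e-08), and Pcna, the replication clamp, from 9372 ± 231 to 4435 ± 102 in VC and from 9476 ± 373 to 3868 ± 253 in Bub1KO. Double-strand break repair genes fell in 27 of 42 cases in VC and rose in 4 (33 adjusted over the list alone; median -0.46, camera adjusted p = 4.62e-06, or adjusted p = 0.134 with an estimated correlation). In Bub1KO they fell in 30 and rose in 4 (35 adjusted over the list alone; median -0.55, camera adjusted p = 7.79e-08, or adjusted p = 0.079 with an estimated correlation). Brca1 (2714 ± 93.6 to 5296 ± 95.2 in VC) and Xrcc5 rose in both. The other risers, named after their values were seen, were Rad51d and Prkdc in VC and Lig4 and Trp53bp1 in Bub1KO. Stress granule protein genes fell in 24 of 33 cases in each genotype and rose in 1 in VC (25 adjusted over the list alone; median -0.43, camera adjusted p = 8.86e-07, and 0.0371 with an estimated correlation). In Bub1KO 2 rose (26 adjusted over the list alone; median -0.45, camera adjusted p = 3.46e-07, and 0.0377 with an estimated correlation), with Hnrnpa1 and Tardbp showing the clearest falls. The rises, Atxn2 in both and Zfand1 in Bub1KO, were weak, and the calls of Atxn2 in VC and of Zfand1 each ended in 8 settings (at most 0.129 and 0.118).

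The histone genes that were tested went against the other proliferation genes. Only 16 of the 69 listed histone genes in the data passed the filter, which a gene can pass through irradiated libraries alone. Of 16 replication-dependent histone genes 10 rose and 1 fell in VC (11 adjusted over the list alone; median 1.14, camera adjusted p = 0.00209, and 0.0244 with an estimated correlation). In Bub1KO 8 rose and 2 fell (10 adjusted over the list alone; median 0.78, camera adjusted p = 0.0349, or adjusted p = 0.079 with an estimated correlation). The linker histone gene Hist1h1c went from 327 ± 24.1 to 1378 ± 55.4 in VC and Hist1h1e from 74.7 ± 19.1 to 24.9 ± 11.8. The falls in Bub1KO were Hist1h1e and Hist1h2bb, and the latter call ended in 9 settings. Histone genes resemble each other closely and their reads may be shared. The list's call in Bub1KO ended with library sizes without the 20 most abundant genes (0.0782), with the 6 libraries compared alone (0.0637) and without a filter (0.777).

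Pigment, mesenchymal and matrix genes rose side by side. Melanocyte differentiation had 14 higher and 2 lower (Pax3 and Mlana) of 23 in VC (17 adjusted over the list alone; median 0.50, camera adjusted p = 8.79e-05, and 0.0107 with an estimated correlation). In Bub1KO 11 were higher and 1 (Pax3) lower (12 adjusted over the list alone; median 0.34, camera adjusted p = 0.00508, and 0.0322 with an estimated correlation). Trpm1 went from 309 ± 38.0 to 1604 ± 62.8 in VC, Oca2, a melanosome transporter gene, from 12.9 ± 2.42 to 111 ± 5.79, Tyr by 1.35 in VC (limma adjusted p = 2.94e-07) and 0.88 in Bub1KO (limma adjusted p = 1.33e-05), and Mitf by 0.27 in VC (limma adjusted p = 0.0087) and -0.09 in Bub1KO (limma adjusted p = 0.331). The falls of Pax3 and Mlana in VC and that of Tgfb2 in Bub1KO ended with library sizes without the 20 most abundant genes, among other settings for the last 2 (at most 0.0518, 0.0664 and 0.0957). Dedifferentiated melanoma markers had 8 of 9 higher in VC (8 adjusted over the list alone; median 1.11, camera adjusted p = 0.000256, and 0.0146 with an estimated correlation). In Bub1KO 7 were higher (7 adjusted over the list alone; median 1.51, camera adjusted p = 0.000187, and 0.0141 with an estimated correlation). Loxl2 went from 41.9 ± 8.56 to 144 ± 10.4 in VC. Extracellular matrix and TGF-beta response had 14 higher and 4 lower of 25 in VC (19 adjusted over the list alone; median 0.76, camera adjusted p = 0.00227, and 0.0206 with an estimated correlation). In Bub1KO 13 were higher and 2 (Thbs1 and Tgfb2) lower (18 adjusted over the list alone; median 0.64, camera adjusted p = 0.0129, and 0.0377 with an estimated correlation). Sparc went from 18666 ± 1882 to 53225 ± 2876 in VC. Mmp14, Thbs1 and, named after their values were seen, Tgfb2 and Skil were the members that fell in VC. Among the fibroblast and endothelial markers Postn (402 ± 21.7 to 1649 ± 39.2) and Vwf (12.4 ± 2.84 to 191 ± 14.6) rose and Pdgfra fell (116 ± 28.0 to 42.1 ± 1.86) in VC.

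The integrated stress response moved apart in the 2 genotypes. In VC 14 of 28 rose and 4 fell (18 adjusted over the list alone; median 0.37, camera adjusted p = 0.00211, or adjusted p = 0.334 with an estimated correlation), with Atf3, a stress-induced transcription factor, going from 148 ± 12.8 to 551 ± 39.6. In Bub1KO 5 rose and 15 fell (20 adjusted over the list alone; median -0.54, camera adjusted p = 0.00132, or adjusted p = 0.311 with an estimated correlation), with Mthfd2, a mitochondrial folate enzyme gene, going from 9757 ± 1016 to 4281 ± 519. In VC the falls were Psat1, Slc7a5 (ended in 3 settings, at most 0.0827) and, named after their values were seen, Gars and Atf4. In Bub1KO the rises were Sesn2, Slc7a3 and, named after their values were seen, Ppp1r15a, Ddit4 and Ddit3. Cell death effectors had 10 higher and 2 lower (Mcl1 among them) of 20 in VC (12 adjusted over the list alone; median 0.32, camera adjusted p = 0.00807, and 0.0405 with an estimated correlation). In Bub1KO 11 were higher and 1 lower (12 adjusted over the list alone; median 0.29, camera adjusted p = 0.0105, and 0.0446 with an estimated correlation). As the list includes anti-apoptotic Bcl2l1 (1169 ± 61.8 to 3065 ± 70.3 in VC), its calls do not show more death. The Mcl1 call ended in 7 settings (at most 0.241). Mitochondrially encoded mRNAs had 6 of 7 higher in VC (6 adjusted over the list alone; median 0.46, camera adjusted p = 0.0133, or adjusted p = 0.299 with an estimated correlation). In Bub1KO 7 of 7 were higher (7 adjusted over the list alone; median 0.42, camera adjusted p = 0.00451, or adjusted p = 0.236 with an estimated correlation). The call in VC ended without a filter (0.0549). Abundant noncoding RNAs had 4 higher and 2 lower of 7 in VC (6 adjusted over the list alone; camera adjusted p = 0.427). In Bub1KO 3 were higher and 2 lower (5 adjusted over the list alone; camera adjusted p = 0.343). The falls were Snhg1 and Gas5 in VC and Rn7sk and Snhg1 in Bub1KO. Snhg12 rose in both and Rn7sk in VC, and both are named after their values were seen. Neat1 and Malat1 rose in both, Malat1 going from 23407 ± 1570 to 49047 ± 4256 in VC.

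Among the largest rises with irradiation were Spp1, the osteopontin gene (5.62 ± 1.60 to 251 ± 22.5 in VC and 9.35 ± 1.89 to 447 ± 33.7 in Bub1KO), Cpz, a carboxypeptidase gene (6.01 ± 3.17 to 204 ± 3.90 and 1.93 ± 0.248 to 118 ± 12.1). Another was the complement protease gene C1s1 in VC (11.5 ± 5.36 to 373 ± 44.6). The largest falls were smaller in size, with the mitotic kinase gene Pbk going from 2536 ± 130.2 to 861 ± 12.1 in VC and Hmgb2, a chromatin protein gene, from 5946 ± 643 to 1807 ± 99.3 in Bub1KO. Limma called 7861 genes in VC, 4065 higher and 3796 lower, and 7269 in Bub1KO, 3746 higher and 3523 lower. At 2-fold or more 1747 were higher and 284 lower in VC, and 1514 higher and 287 lower in Bub1KO. With library sizes that leave out the 20 most abundant genes the split was 4966 higher and 2774 lower in VC and 4572 and 2652 in Bub1KO. The median change of all genes moved from 0.02 to 0.12 in VC and from 0.03 to 0.12 in Bub1KO, so changes within about 0.1 log2 depend on the scaling. Genes higher with irradiation in both genotypes numbered 2979 and genes lower in both 2918, where 1030 and 908 would be shared by independent lists. There 25 went opposite ways, and the Pearson correlation across genes was 0.85.

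**Figure D3:**
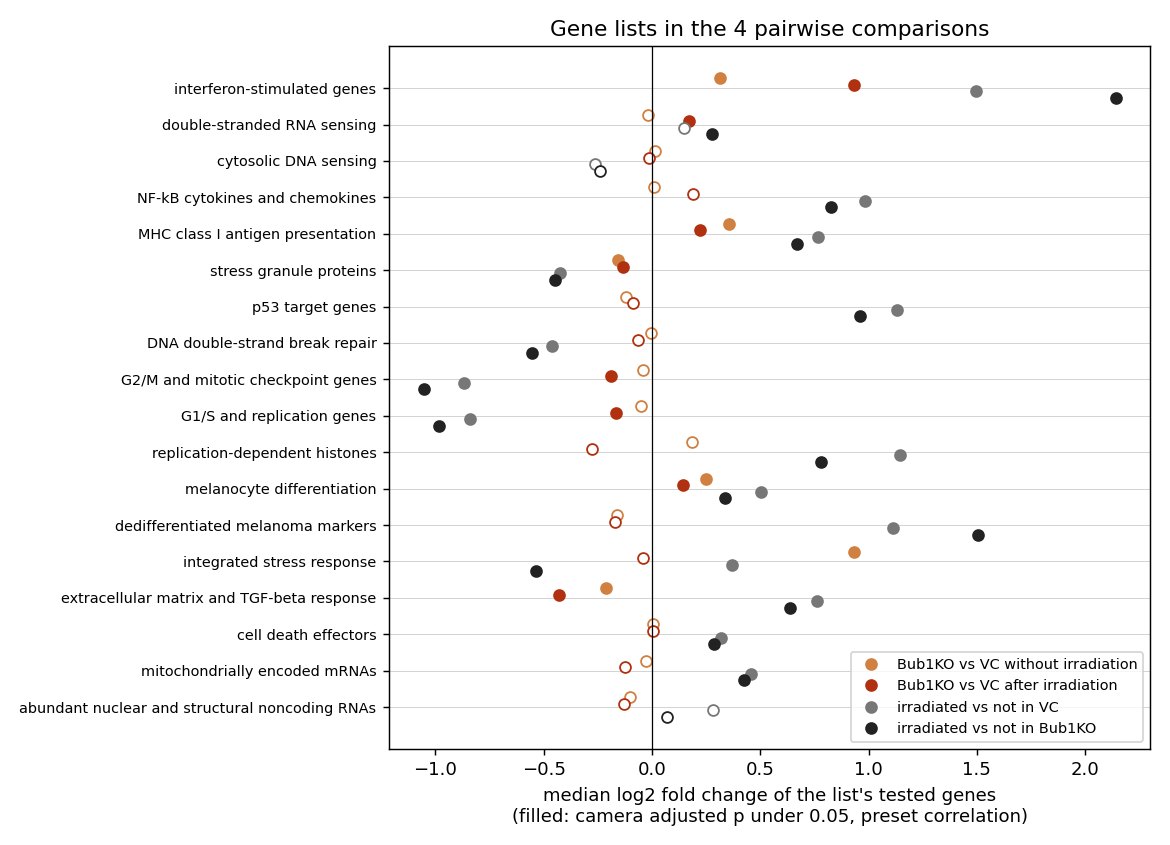
Median log2 fold change (x axis) of each gene list with at least 5 tested genes (y axis) in the 4 pairwise comparisons (colours), filled where the camera adjusted p was under 0.05 with the preset correlation. Interferon-stimulated genes lie at 0.31, 0.93, 1.495 and 2.14, and the integrated stress response at 0.93, -0.04, 0.37 and -0.54, for Bub1KO against VC without and after irradiation and for irradiation in VC and in Bub1KO.

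The interaction asks whether the response to irradiation itself differed between genotypes. The integrated stress response differed most: 17 of 28 members had a negative interaction past the threshold and 0 a positive one, with a median of -0.95 (25 adjusted over the list alone, all negative; camera adjusted p = 6.88e-40, and 0.0185 with an estimated correlation). Trib3 went up with irradiation in VC (271 to 936) and was at 2261 and 951 in Bub1KO (interaction -2.98, SE 0.348, limma adjusted p = 0.00119). Asns, asparagine synthetase, went from 4268 ± 269.9 to 4626 ± 66.1 in VC and from 8370.4 ± 682 to 4515 ± 179.7 in Bub1KO (-1.006, limma adjusted p = 0.000754), and Atf3 from 148 to 551 and from 407 ± 69.7 to 455 ± 40.5 (-1.72, limma adjusted p = 0.000754). Over the 12 fits that each leave out 1 library 10 to 25 members had a negative interaction past the threshold, 25 without the untreated Bub1KO replicate that stood apart.

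Interferon-stimulated genes had a positive median interaction of 0.47 (camera adjusted p = 6.23e-14, or adjusted p = 0.0897 with an estimated correlation), with 1 of 46 members past the threshold (21 adjusted over the list alone, 20 positive and 1 negative). That gene was Dhx58, the RIG-I-like receptor LGP2 (GRCm38 chromosome 11, 100694884 to 100704271), at 59.98 ± 0.987 and 117 ± 8.64 in VC before and after irradiation and at 34.7 ± 7.26 and 291 ± 51.7 in Bub1KO (2.09, SE 0.237, limma adjusted p = 0.00119). It was also the 1 of 24 genes of double-stranded RNA sensing that passed (2 adjusted over the list alone; median 0.19, camera adjusted p = 0.000106, and 0.0185 with an estimated correlation). For the single readouts the difference in response did not pass: Isg15 0.17 (limma adjusted p = 0.822), Ifit1 0.35 (0.7), Ddx58 0.32 (0.281), Ifih1 0.08 (0.887), H2-K1 0.15 (0.833) and Cxcl10 0.76 (0.101). Without the untreated Bub1KO replicate that stood apart 15 members passed. The chemokine gene Ccl5 responded less in Bub1KO (-0.87, SE 0.175, limma adjusted p = 0.0436), a call that ended in 15 of the settings tried, 10 of them leaving out 1 library, with adjusted p of at most 0.158. It was the 1 change among 18 NF-kB genes (2 adjusted over the list alone; camera adjusted p = 0.512).

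Lists of proliferation genes had small negative interactions with 0 single genes past the threshold by limma or adjusted over the list alone: G2/M and mitotic checkpoint genes (median -0.19, camera adjusted p = 3.29e-05, or adjusted p = 0.151 with an estimated correlation), G1/S and replication genes (median -0.14, camera adjusted p = 3.29e-05, or adjusted p = 0.142 with an estimated correlation) and double-strand break repair (median -0.11, camera adjusted p = 0.00955, or adjusted p = 0.508 with an estimated correlation). Replication-dependent histones had a median of -0.51 with 0 past the threshold (2 adjusted over the list alone; camera adjusted p = 0.0194, or adjusted p = 0.0986 with an estimated correlation), and melanocyte differentiation a median of -0.16 with 1 negative, Rab27a (6 adjusted over the list alone; camera adjusted p = 0.0214, or adjusted p = 0.0986 with an estimated correlation). Without the untreated Bub1KO replicate that stood apart the calls of repair (0.271), histones (0.256) and melanocyte genes (0.0725) ended. The p53 targets had 1 member past the threshold, Sesn2, which also stands in the stress response list (3 adjusted over the list alone; median -0.03, camera adjusted p = 0.941). Cdkn1a (0.31, limma adjusted p = 0.341), Mdm2 (-0.08, 0.836), Mitf (-0.36, 0.175) and Tyr (-0.47, 0.206) did not pass. Cell death effectors had 1 negative gene, Hrk, a BH3-only gene (1.13, 23.5, 4.51 and 4.81 in untreated VC, irradiated VC, untreated Bub1KO and irradiated Bub1KO; 1 adjusted over the list alone; camera adjusted p = 0.898), and abundant noncoding RNAs 1, Rn7sk (2 adjusted over the list alone; camera adjusted p = 0.145). The calls of Rab27a, Hrk and Rn7sk each ended in 4 settings (adjusted p of at most 0.0606, 0.0615 and 0.0606).

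No member passed by limma, and no list by camera, in MHC class I antigen presentation (0 adjusted over the list alone; camera adjusted p = 0.838), stress granule proteins (0; 0.993), cytosolic DNA sensing (0; 0.454), extracellular matrix and TGF-beta response (2; 0.109), dedifferentiated melanoma markers (1; 0.941) and mitochondrially encoded mRNAs (1; 0.898). The median and mean of the last 2 lists differed in sign (-0.01 and 0.08, -0.02 and 0.09), and the stress granule list had a median of -0.001 with camera upward. Without irradiated VC replicate 1 the matrix list passed, downward (camera adjusted p = 0.0398). In all, 81 genes had an interaction past the threshold by limma, 20 positive and 61 negative, against 1784 at an unadjusted p under 0.05. The count was 1447 without the untreated Bub1KO replicate that stood apart, 33 without irradiated VC replicate 1, 275 with DESeq2 and 418 with GC trends removed.

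Markers of other cell types were few. Of 16 leukocyte and macrophage markers 3 were tested (Cd68, Lyz2 and Fcer1g), while Ptprc, Adgre1, C1qa, C1qc, Cd3e, Nkg7 and Tyrobp had means under 1 normalized count in every group. Cd68 was also higher in irradiated Bub1KO than in irradiated VC (0.94, limma adjusted p = 0.000135) and the interaction was 1.24 (limma adjusted p = 0.0172, at most 0.0706 in the 6 fits that leave out 1 library and end the call), and Fcer1g lay between 16.5 and 21.8 in all groups. Of 13 fibroblast and endothelial markers 3 were tested (Postn, Vwf and Pdgfra); Postn was higher in irradiated Bub1KO than in irradiated VC (0.27, limma adjusted p = 0.0117), and 0 had an interaction past the threshold. Of 9 keratinocyte and epithelial markers Cdh1 alone was tested, at 64.6 ± 11.1 in untreated VC, 86.7 ± 11.1 in untreated Bub1KO, 87.2 ± 13.2 in irradiated VC and 124 ± 8.54 in irradiated Bub1KO, and limma called it with irradiation in both genotypes and between the irradiated genotypes (adjusted p of 0.04, 0.0176 and 0.0165). The Postn call ended in 4 settings and those of Cdh1 in 7, 2 and 4 (adjusted p of at most 0.109, 0.155, 0.072 and 0.0948).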

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

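Among the tests below, the one of a single library, the one of leukocyte RNA and the one of variation between libraries were chosen after the results were seen, as was the removal of GC trends as a setting. The results listed here drew attention because the response to irradiation differed between VC and Bub1KO by the interaction test, which 81 genes passed (33 without irradiated VC replicate 1, 1447 without untreated Bub1KO replicate 1). Of 100 orders of the residuals of a model without interaction, the real one included, 2 gave as many genes, a share under 0.05. The other such order gave 652 genes, which points to a structure of the samples, whose source was not tested. The share assumes residuals that can be exchanged between libraries, while untreated Bub1KO replicate 1 stood apart, so it cannot exclude chance.

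Lists passed with median interactions of 0.474 for interferon-stimulated genes, 0.193 for double-stranded RNA sensing, -0.108 for double-strand break repair, -0.185 for G2/M and mitotic checkpoint genes, -0.137 for G1/S and replication genes, -0.509 for replication-dependent histones, -0.158 for melanocyte differentiation and -0.947 for the integrated stress response. With an estimated correlation the lists of double-stranded RNA sensing and of the integrated stress response passed. The calls of repair, histones and melanocyte genes ended without untreated Bub1KO replicate 1 (camera adjusted p = 0.271, 0.256 and 0.0725). Those of histones and melanocyte genes also ended without untreated VC replicate 2 (0.101 and 0.101), that of histones at a CPM of at least 1 in 3 libraries and with GC trends removed (0.0758 and 0.0786), and that of repair without irradiated Bub1KO replicate 1 (0.0543).

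Single genes with a positive interaction were Adam12 (1.21), Cd68 (1.24), Dhx58 (2.09), Etv5 (1.46), Lgr6 (1.8), Lifr (1.26), Pygm (1.75) and Slc17a9 (1.47). Those with a negative one were Ankdd1b (-1.79), Asns (-1.01), Atf3 (-1.72), Brd3os (-1.85), Ccl5 (-0.868), Ces2e (-2.43), Chac1 (-2.94), Hrk (-3.33), Hs3st1 (-1.73), Nupr1 (-2.11), Rab27a (-0.541), Rn7sk (-1.67), Sesn2 (-1.27), Trib3 (-2.98) and Uqcrq (-2.32). Brd3os by its name lies opposite Brd3, so its reads are uncertain. The calls of Ankdd1b, Ccl5, Cd68, Etv5, Hrk, Lgr6, Lifr, Rab27a, Rn7sk and Uqcrq ended in at least 1 setting that leaves out 1 library, with adjusted p over all settings of at most 0.0891, 0.158, 0.0706, 0.0503, 0.0615, 0.133, 0.14, 0.0606, 0.0606 and 0.135.

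Integrated stress response genes were higher in Bub1KO than in VC without irradiation and not after it. Over the 12 fits that each leave out 1 library the median interaction was at most -0.799, which argues against a single library as the cause. With each library's GC trend removed it was -0.869, which argues against GC content as the whole cause. A difference in the state of the untreated cultures, such as nutrients or density, cannot be told apart from an effect of the genotype, since no label gives it. An effect of Bub1 disruption stays open as a hypothesis, untested against other differences between the VC and Bub1KO cells.

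Interferon-stimulated genes were higher in irradiated Bub1KO than in irradiated VC. With GC trends removed the median change was 0.913, which argues against GC content as the whole cause. The test of leukocyte RNA summed the means of 8 leukocyte genes (Ptprc, Adgre1, C1qa, C1qb, C1qc, Cd3e, Nkg7 and Tyrobp). The sum was 0 in irradiated Bub1KO and 1.61 in irradiated VC, while the mean of Irf7 rose by 97.6. This argues against RNA of leukocytes that express these 8 genes. They were chosen after the values were seen and leave out the 3 tested markers of the leukocyte list. Of those, Cd68, a macrophage marker that other cells also express, was at 216 in irradiated Bub1KO against 113 in irradiated VC. Lyz2 was at 62.3 against 68.8 and Fcer1g at 18.8 against 16.5. Reads shared between related genes such as Ifit3 and Ifit3b were not tested. An effect of Bub1 disruption stays open as a hypothesis, as do other differences between the 2 kinds of cells.

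Rpl36 and Uqcrq were lower in irradiated Bub1KO than in irradiated VC. With GC trends removed Rpl36 changed by -1.81 (SE 0.159, adjusted p = 3.83e-06) against -2.04 (SE 0.21) before, and Uqcrq by -1.71 against -1.66. GC content is thereby argued against as the whole cause. A share in the difference of Rpl36 stays open because its value lies beyond the bound set beforehand, -1.5, by less than 2 SE, the margin first set (1 SE, which the value exceeds, was tried and dropped after the value was seen). Within untreated Bub1KO, which holds the replicate that stood apart, the highest value was 2.54 times the lowest for Uqcrq and 7.28 times for Rpl36. Within untreated VC these ratios were 1.87 and 3.16. The means of the irradiated groups differed by folds of 3.36 and 4.39, a measure unlike the ratio of highest to lowest. The irradiated groups did not overlap. Rpl36 ran from 7789 to 17940 in VC and from 2451 to 2804 in Bub1KO, and Uqcrq from 2257 to 5003 and from 974 to 1037. Variation between libraries and a change with genotype cannot be told apart by this comparison, as in untreated Bub1KO 1 gene exceeds its fold and the other falls short of it.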

How the results depend on the processing

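The fits with edgeR, with TMM factors, with all 12 libraries in the genotype comparisons, with GC trends removed and the leave-one-out fits of the overlap were chosen as alternatives after seeing the data. The design had named edgeR with TMM factors on 12 libraries for raw counts and limma-trend on 6 for normalized values. Genotype counts without irradiation (591) were 1831 with DESeq2, 1759 with edgeR and 1769 with limma on 12 libraries, 1690 with GC trends removed (2694 also without untreated Bub1KO replicate 1), 329 without a filter, 312 with replicate numbers as blocks and 216 at 2-fold. After irradiation (4512) they were 2539, 2454 and 2105 in the same 3 fits, 2062 without a filter and 404 at 2-fold. On the 6 libraries compared edgeR gave 693 and 4560 (TMM factors in limma: 578 and 4531), so the spread taken from the other libraries, not the tool, moves these counts. At 2-fold irradiation gave 2031 in VC and 1801 in Bub1KO. The interaction (81) gave 275 with DESeq2, 47 with blocks, 418 with GC trends removed and 40 at 2-fold. The shared genotype calls (447, 89.7 expected) were 936 (167) with DESeq2, over genes given an adjusted p in both,, 890 (146) with edgeR, 828 (127) with 12 libraries, 255 (43.2) with blocks and 1102 (285) with GC trends removed. Lists past the threshold (6, 8, 15, 16 and 8) were 0, 0, 12, 12 and 2 with an estimated correlation. With blocks the p53 list passed after irradiation (0.0493). Leaving out 1 library gave 172 to 2736 genes without irradiation, the highest without untreated Bub1KO replicate 1 (all 591 among them) and 185, 172, 242, 301 and 298 without VC 1, 2, 3 and Bub1KO 2 and 3. After irradiation it gave 3045 (without Bub1KO 2) to 4744, for irradiation 6733 to 7120 in VC and 6141 to 7567 in Bub1KO, for the interaction 33 (without irradiated VC 1) to 1447 (without untreated Bub1KO 1, all 81 among them) and for the overlap 147 (25.8 expected) to 1290 (417). Lists then numbered 6 to 7, 8 to 9, 15, 16 and 5 to 9. Where 1 library is left out its group keeps 2, fewer than the full design. Except as stated, the cause was not tested. Values of named genes gave the same call 5105 times, a call lost 307 times, a call gained 27 times and a reversed one 0 times. Of called named genes 21 of 39, 52 of 77, 68 of 79, 73 of 79 and 13 of 23 kept the call in all settings run. Deviations of libraries with the same replicate number correlated at -0.193 to 0.0549. No pairing by number was seen, but unlike numbers were not correlated for comparison, so its absence is not shown. The interferon ligands, at 0 or 1 read in total, were not testable at this depth.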

Other observations

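In this part the list of hypoxia-induced genes was chosen after Car9 and Ndufa4l2 had been seen, and the gene types were described after their values were seen. Cells induce Car9 and Ndufa4l2 when oxygen is short. Ndufa4l2 was among the largest rises without irradiation (4.49 in VC and 41.5 in Bub1KO) and Car9 among the largest after it (196 in VC and 889 in Bub1KO). The hypothesis that a wider hypoxia response went with them was tested on 24 other hypoxia-induced genes, 22 of them past the filter and 0 of them in another list. The lower of the 2 medians was 0.438 (without irradiation, quartiles 0.251 and 0.704; 8 higher and 0 lower; camera p = 1.22e-11, and 0.0594 with an estimated correlation). After irradiation the median was 0.68 (quartiles 0.359 and 0.982; 20 higher and 1, Pfkfb3, lower; camera p = 7.44e-17, and 0.0587 with an estimated correlation). Vegfa went from 310 to 710 and from 682 to 1159, Pdk1 from 901 to 1872 and from 1159 to 2623, and Bnip3 from 567 to 1410 and from 815 to 2223 between VC and Bub1KO, chosen after their values were seen. These values are consistent with a hypoxia response (0.438 against a bound of 0.3 set before the medians were computed). Whether it follows from the genotype or from denser or otherwise different cultures stays open, since each genotype label stands for 1 kind of cell.

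A gain or loss of whole chromosomes in Bub1KO was tested by the median change of each autosome's genes relative to all autosomal genes. The largest size in either treatment was 0.0626 (chromosome 12, upward, after irradiation), under the bound of 0.15 for every autosome. In a simulated chromosome shift of 0.585 the same measure gave 0.571, and 0.0247 at most on the others. A gain or loss of a whole autosome shared by the cells of Bub1KO is argued against, while shorter segments were not tested.

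The 412 tested lincRNA genes had a median change of 0.59 in VC and 0.48 in Bub1KO, and 366 antisense genes 0.504 and 0.39, against 0.02 and 0.03 for all tested genes. In VC 185 lincRNA genes were higher and 41 lower, and in Bub1KO 162 and 30. Of 999 processed pseudogenes (median -0.247 in VC and 0.0221 in Bub1KO) 45 were higher and 134 lower in VC and 57 and 94 in Bub1KO, and of 427 unproven genes of the type TEC (-0.0855 and 0.154) 40 and 59 in VC and 49 and 19 in Bub1KO. The difference between gene types was not tested, nor was a cause.

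Of 10 splits of 6 libraries into 3 and 3, the real one included, 1 gave as many genes as the real split in each of the 4 pairwise comparisons, which is too few splits for a share under 0.05. The real counts were 591, 4512, 7861 and 7269 and the highest of the other splits gave 0 in each.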
